A study of Caenorhabditis elegans with 9 samples.

How the data were processed

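RNA abundance was measured by sequencing in 9 libraries of whole Caenorhabditis elegans adults, harvested 48 hours after the last larval stage. Worms lived on agar plates from 1 batch that held nicotinic acid, 1-methylnicotinamide (MNA) or water, with 3 libraries per group. The labels give the nicotinic acid dose in conflicting ways: the sample source reads 1 mM and the treatment protocol reads 1 nM. MNA was given at 1 µM, so the doses of the compounds differ under either reading. Total RNA was extracted with phenol and chloroform, and libraries were made from 2 µg of it with a TruSeq RNA kit, with no strand setting stated.

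Per the submitters' processing notes, CASAVA, TopHat 1.4.1 and HTSeq were used upstream. The genome build, the annotation version, the HTSeq settings and any filters are not given in the sources used here, and no coordinates are printed for that reason. The deposited counts are whole numbers per gene and library with no normalization. The deposited RPKM values are, by the values themselves, the counts scaled by the library total and by a gene length. This held to within 0.01 bases of a whole-number length in all 15512 genes with counts in all libraries. RPKM was used in an alternative fit, and every other result rests on the counts.

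The count table held 45461 entries, of which 23145 were above 0 in at least 1 library. The identifiers of 44080 entries matched the gene reference used for symbols, and these held 99.3% of all counts. Library totals ran from 18501261 to 31247605 counts, so that 3 counts, taken as the detection floor, correspond to 0.096 to 0.162 CPM, the count of a gene scaled to a common library total. Floors and intervals cover counting error only, or the fitted error of the model where they come from it, and not the identity of reads shared between overlapping genes or members of gene families. Families such as the glutathione S-transferases, collagens and major sperm proteins hold close paralogs, and how such reads were assigned is not stated.

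Genes were kept with the edgeR filter filterByExpr by group at a minimum count of 10, which left 13985 genes with 99.95% of the counts. One edgeR quasi-likelihood model (version 4.0.16 in R 4.3.3, robust fit, TMM factors from 0.963 to 1.028, a term for group and none for replicate number) was fitted to all 9 libraries. The 3 groups were compared in pairs, each test was two-sided, and p-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. Changes are log2 fold changes with the standard error (SE) of the model, and group means are CPM with the standard deviation (SD) over n = 3 libraries. The labels do not say that the replicates are separate cultures, so the p-values measure the spread between these samples.

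Gene lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 44 lists, of 45 written, that had at least 5 tested members. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes, while fry asks whether the genes of a list move, on balance, one way, or in either direction for its mixed form. The lists covered NAD and one-carbon metabolism, stress and immune responses, energy metabolism, cell types and gene families. A gene could sit in several lists.

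The groups, comparisons, tests, gene lists, alternatives and the rule for named genes were made before the data were examined. The rule took, per comparison, the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 CPM over all libraries and no overlap between the libraries of the groups. It added the 4 tested members with the smallest p of each list that passed, a fixed set of 14 genes in every comparison, and, between the compounds, every gene of the first kind from the comparisons with control. Genes named outside this rule are said to be chosen after their values were seen.

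The model was tested on simulated data with the depth of each library, in which known genes were changed. The mean and spread of each gene came from the fit of all 9 libraries and were the same for each comparison. At a 2-fold change, 76.1% of changed genes were recovered for nicotinic acid against control, 77.6% for MNA against control and 76.1% between the compounds. At a 1.5-fold change the shares were 52.2%, 62.7% and 46.3%, and false calls made up 8.2%, 3.7% and 5.3% of all calls. Each share of recovered genes rests on 67 genes from a separate random draw, so the shares do not rank the comparisons. No list was called in the simulated comparison without changes (0 of 44). The simulated genes varied independently of each other, so this does not cover lists whose genes vary together. In the data the estimated correlation of the muscle list, for example, was 0.614 for nicotinic acid against control.

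Alternatives covered a block for replicate number, other scaling factors, no filter and a stricter filter, DESeq2 1.42.0, limma-voom, fits of the 2 groups compared alone, thresholds of 0.01 and 0.1, limma-trend on the log2 of RPKM with 1 or 0.1 added, and leaving out each of the 9 libraries in turn. A fit without ribosomal RNA genes was chosen after seeing the data. Because both comparisons with control use the same 3 control libraries, the overlap and the correlation between them were set beside simulations of unchanged groups with common controls (100 for the correlation, 20 for the overlap). A further 20 simulations, in which the compounds had unrelated effects, were chosen after the overlap was seen. They gave the log2 fold changes of genes with an unadjusted p below 0.05 to random genes of like expression. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. No library was left out.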

Results

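The study sequenced mRNA of adult Caenorhabditis elegans kept on plates with nicotinic acid, with 1-methylnicotinamide (MNA) or with water as the solvent control, in 3 libraries per group. Nicotinic acid is pyridine-3-carboxylic acid, a vitamin precursor of NAD, and MNA is the N-methylated amide, a product of nicotinamide methylation. Library totals were 22434246, 24588784 and 26655263 counts for the controls, 28747940, 18501261 and 31247605 for nicotinic acid, and 23990697, 27976679 and 27776859 for MNA. Ribosomal RNA genes took 0.221% to 0.631% of the counts and the yolk protein genes (vitellogenins) 4.94% to 7.17%. The common biological coefficient of variation was 0.082, and the first principal components held 39.5% and 23% of the variance. MNA replicate 3 lay at 4.5 on the second, against 22.8 and 25 for the other MNA libraries, and nicotinic acid replicate 1 at -24.1 on the first, against -3.2 and -0.9 for the others of its group.

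The comparison of MNA with control asks which transcripts differ in worms given the methylated amide. The 10 largest rises included 2 glutathione S-transferases, 2 cytochrome P450 genes, 1 UDP-glucuronosyltransferase and 1 flavin-containing monooxygenase. The glutathione S-transferase gene gst-35 (Y1H11.2), whose family conjugates glutathione to electrophiles, rose from 0.779 ± 0.264 to 71.2 ± 27.5 CPM (SD, n = 3), with a log2 fold change of 6.48 (SE 0.46, edgeR quasi-likelihood adjusted p = 0.000764). Its relative gst-21 (ZK697.6) rose by 5.97 on the log2 scale (SE 0.41, edgeR adjusted p = 0.000581), and ugt-37 (F10D2.6), a UDP-glucuronosyltransferase that attaches sugars to small molecules, by 5.65 (SE 0.40, edgeR adjusted p = 4e-04). The flavin-containing monooxygenase gene fmo-5 (H24K24.5) rose from 8.90 ± 0.554 to 234 ± 89.4 CPM (SD, n = 3; log2 fold change 4.72, SE 0.36, edgeR adjusted p = 0.00109). The cytochrome P450 genes cyp-29A3 and cyp-32B1, which encode oxidases, rose by 4.54 (SE 0.28) and 3.83 (SE 0.39).

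The other 4 of the 10 largest rises were F49E12.10 at 5.62, the infection response gene irg-6 (C32H11.1) at 4.63, C32H11.4 at 4.14 and the glucocerebrosidase gene gba-2 (C33C12.8) at 3.99 on the log2 scale. All 10 rises kept an adjusted p below 0.05 in each of the 9 fits that left out 1 library, and limma-voom ended the call of irg-6 (adjusted p = 0.0568).

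**Figure D1:**
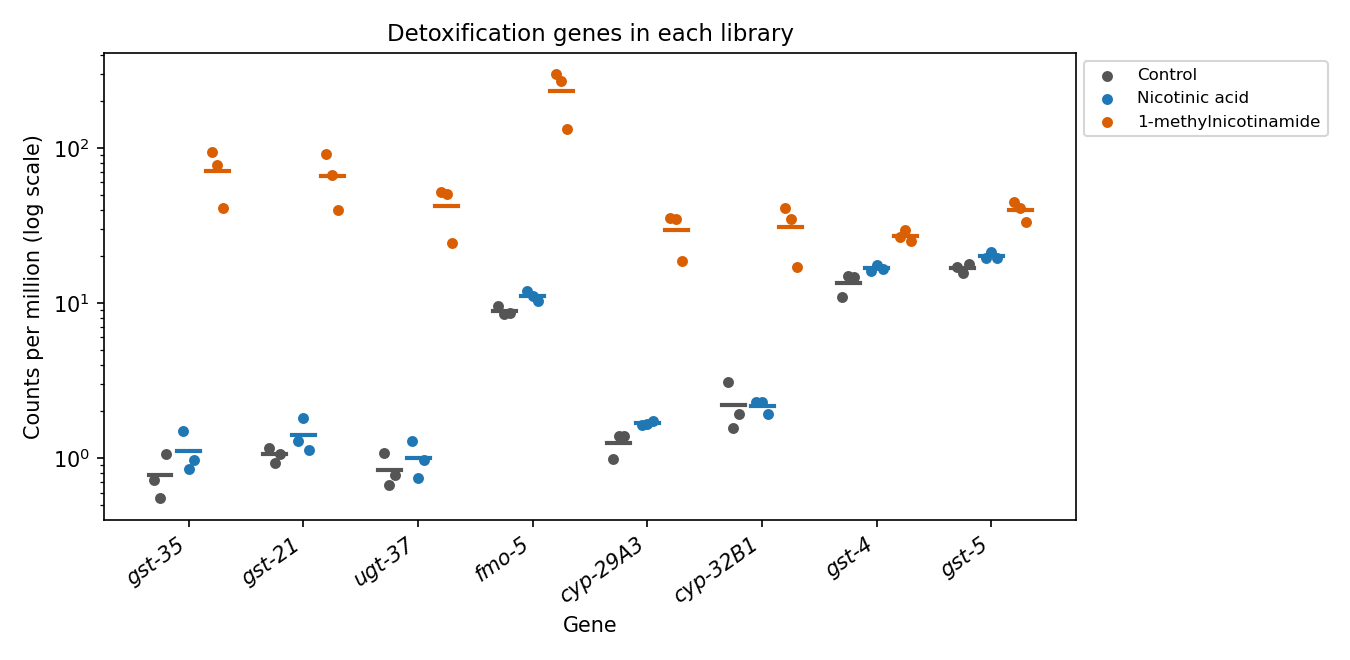
CPM on a log scale for 8 named genes, with 1 point per library and a bar at the mean of each group of 3. For gst-35 the MNA mean was 71.2 CPM against 0.779 in control and 1.11 under nicotinic acid, and for fmo-5 it was 234 against 8.90 and 11.13.

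The fixed lists tested for MNA include families that hold some of the 10 largest rises, so they are not separate evidence from those rises. Of 41 glutathione S-transferases, 15 rose, 0 fell and 26 did not pass, with 17 higher and 2 lower adjusted over the list alone (camera adjusted p = 5.16e-17, and adjusted p = 0.0523 with an estimated correlation). Examples were gst-10 at 1.02 (SE 0.14), gst-5 at 1.24 (SE 0.10) and gst-4, a common reporter of the stress regulator SKN-1, at 1.00 (SE 0.11, edgeR adjusted p = 0.000373). Of 37 SKN-1 and oxidative stress genes, 14 rose and 1 fell, with 17 and 2 adjusted over the list alone (camera adjusted p = 7.08e-09, and adjusted p = 0.196 with an estimated correlation). That list shares glutathione S-transferases with the family list, and skn-1 itself was at 0.02 (95% interval -0.09 to 0.13). Of 30 short-chain dehydrogenases, 8 rose and 1 fell, with 10 and 2 adjusted over the list alone, and dhs-19 went from 24.5 ± 1.66 to 146 ± 46.9 CPM (SD, n = 3). The camera adjusted p of that list was 3.83e-07, against an adjusted p = 0.296 with an estimated correlation. Of 63 cytochrome P450 genes, 11 rose and 3 fell, with 12 and 6 adjusted over the list alone (camera adjusted p = 0.00496, and adjusted p = 0.296 with an estimated correlation). The median of that list was -0.039 while its mean was 0.341 and its test pointed up, and cyp-13A10 (3.28, SE 0.24) and cyp-25A3 (3.40, SE 0.29) were among the members that rose. In the cytochrome P450 family 0 fell without MNA replicate 1 or 2, 1 without control replicate 1 or 3, and 6 without MNA replicate 3.

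Of 60 UDP-glucuronosyltransferases, 9 rose and 2 fell under MNA, with 12 and 7 adjusted over the list alone (camera adjusted p = 0.00993, and adjusted p = 0.322 with an estimated correlation). Its median was 0.04 and its mean 0.281. The call of that list was lost without control replicate 3 (adjusted p = 0.0529), and in the UDP-glucuronosyltransferase family list 5 members rose without MNA replicate 2 and 5 fell without MNA replicate 3. Of 14 DAF-16-repressed genes, which go down when insulin signalling is low, 5 rose and 1 fell, with 6 and 3 adjusted over the list alone (camera adjusted p = 6.04e-06, and adjusted p = 0.0677 with an estimated correlation). The median of that list was 0.022 and its mean 0.622, with 7 of 14 above 0, and the median ran from -0.043 without MNA replicate 1 to 0.057 without MNA replicate 3 in the DAF-16-repressed genes. The members that rose included F55G11.2 (2.27, SE 0.18), dod-17 (1.66, SE 0.14) and ugt-16 (1.75, SE 0.17). In 20 immune effectors that depend on the p38 kinase PMK-1, 5 rose and 5 fell (camera adjusted p = 0.56).

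Cuticle genes also moved under MNA. In the hatched larva and moult list, whose genes act in cuticle renewal, 12 of 34 rose and 2 fell, with 14 and 3 adjusted over the list alone (camera adjusted p = 6.7e-09, and adjusted p = 0.476 with an estimated correlation). The cuticle collagens dpy-13 (2.49, SE 0.29), sqt-1 (2.39, SE 0.29) and dpy-8 (1.87, SE 0.20) rose. In the hatched larva and moult list 0 fell without control replicate 1, control replicate 3 or MNA replicate 2. In the collagen family 34 of 112 rose and 4 fell, with 49 and 11 adjusted over the list alone (camera adjusted p = 7.8e-14, and adjusted p = 0.296 with an estimated correlation). Of the collagen family 19 members rose without MNA replicate 1, 18 without MNA replicate 2, and 52 without nicotinic acid replicate 1. In it 2 fell without MNA replicate 2. The genes lower under MNA included other cuticle genes: dpy-17 (F54D8.1), a collagen that shapes the body, fell from 153 ± 42.5 to 21.7 ± 5.65 CPM (SD, n = 3; log2 fold change -2.82, SE 0.47, edgeR adjusted p = 0.0188). The largest falls were in col-121 at -3.86, dsl-6, a Notch ligand relative, at -3.77 and ins-19, an insulin-like peptide, at -3.75, followed by Y41D4B.6, the intermediate filament gene ifa-3, the hatching protease gene hch-1, the collagen gene dpy-14, R09E10.5, the cuticlin gene cut-3 and dpy-17. Of these 10, ins-19, Y41D4B.6 and ifa-3 kept their calls in each of the 9 fits that left out 1 library. The other 7 lost theirs without MNA replicate 2, 6 of them also without control replicate 3 or MNA replicate 1, and 3 without MNA replicate 3, without control replicate 1 or without nicotinic acid replicate 3. For hch-1 the loss also came without control replicate 2, and the highest adjusted p ran from 0.051 for dsl-6 to 0.143 for cut-3. All 10 passed in limma-voom, and cut-3 lost its call when the 6 libraries were fitted alone.

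Smaller list shifts under MNA were as follows. Cytosolic ribosomal protein genes had 0 of 79 past the threshold in edgeR, DESeq2 and limma-voom and 2 at an unadjusted p below 0.05, with 74 above 0 and a median of 0.09 (camera adjusted p = 9.15e-06, and adjusted p = 0.826 with an estimated correlation). Oxidative phosphorylation had 1 of 45 higher, with 43 above 0 (camera adjusted p = 0.00993, and adjusted p = 0.766 with an estimated correlation), and was lost without control replicate 1 or MNA replicate 3 (highest adjusted p = 0.151). Its member past the threshold, nduf-9, was at 0.19 and lost the call without control replicate 1 or 3, any 1 MNA library or nicotinic acid replicate 2 (highest adjusted p = 0.206) and in limma-voom (adjusted p = 0.053). The propionate shunt, an alternative route that breaks down propionate, had 1 of 7 lower and 3 adjusted over the list alone (camera adjusted p = 0.0109, and adjusted p = 0.498 with an estimated correlation). In the propionate shunt 3 were lower without MNA replicate 3. Its first enzyme gene, acdh-1, fell by 0.27 on the log2 scale (SE 0.06, edgeR adjusted p = 0.0228), a call lost without control replicate 1, MNA replicate 1 or MNA replicate 2 (highest adjusted p = 0.133). Transthyretin-related genes had 5 of 48 lower and 1 higher, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.0125, and adjusted p = 0.436 with an estimated correlation). Without MNA replicate 1 or 2 there were 2 lower in the transthyretin-related family.

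Across all 13985 genes tested, 508 rose and 528 fell under MNA (edgeR quasi-likelihood, Benjamini-Hochberg), 310 and 172 of them by at least 2-fold. The unadjusted p was below 0.05 for 2650 genes, and the 3 libraries of a group did not overlap those of the other for 3443 genes (24.6%, where chance gives 10%). There were 228 higher and 141 lower without MNA replicate 2, 269 and 193 without MNA replicate 1, 364 and 291 without control replicate 3, and 408 and 282 without control replicate 1. Without control replicate 2 the lower genes were more, with 362 higher and 581 lower. Camera called 16 of 44 lists (13 up, 3 down). With an estimated correlation it called 0, with 6 at an unadjusted p below 0.05, while fry called 9. Among these were the glutathione S-transferases (fry adjusted p = 0.00147), DAF-16-repressed genes (0.00695), SKN-1 genes (0.00844), short-chain dehydrogenases (0.0279) and collagens (0.0316). The hatched larva and moult list was not called by fry (adjusted p = 0.0797).

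The comparison of nicotinic acid with control asks which transcripts differ in worms given the vitamin. Immune effector genes were lower: catp-3 (C09H5.2), a cation-transporting ATPase gene, fell from 51.7 ± 3.04 to 25.1 ± 1.90 CPM (SD, n = 3; log2 fold change -1.04, SE 0.10, edgeR adjusted p = 0.000478). The lysozyme gene lys-7 (C02A12.4), whose product attacks bacterial walls, fell from 379 ± 5.62 to 248 ± 21 CPM (SD, n = 3; log2 fold change -0.61, SE 0.08, edgeR adjusted p = 0.00335). Of 20 PMK-1-dependent immune effectors 7 fell, 0 rose and 13 did not pass, with 9 lower adjusted over the list alone, among them asp-12, an aspartyl protease gene, at -0.84 and C17H12.8 at -0.49. The camera adjusted p was 2.2e-10, against an adjusted p = 0.206 with an estimated correlation, and pmk-1 itself was at -0.20 (edgeR adjusted p = 0.23).

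Collagen genes of the cuticle rose under nicotinic acid: 37 of 112 were higher and 4 lower, with 66 and 7 adjusted over the list alone (camera adjusted p = 4.61e-31, and adjusted p = 0.206 with an estimated correlation). Those with the smallest p were col-166 at 0.58 (SE 0.06, edgeR adjusted p = 0.000478), col-10 at 0.81 (SE 0.09) and col-167 at 0.94 (SE 0.11), while col-76 fell by 0.80 (SE 0.09). Of the collagen family 20 members rose and 2 fell without control replicate 1, and 17 rose and 1 fell without control replicate 3. In the hatched larva and moult list, which was not called, 7 of 34 rose and 2 fell, with 10 and 8 adjusted over the list alone (camera adjusted p = 0.0729). The 10 largest rises were F27C1.1 at 3.54, the collagens col-49, rol-1, col-138, bli-1 and col-133, the sperm-specific gene ssq-2 at 3.07, Y47G6A.15, gipc-2 and T10E9.4, down to 3.00. All 10 were highest in nicotinic acid replicate 1, as for ssq-2, which had 7.17, 2.51 and 2.32 CPM in the nicotinic acid libraries against a control mean of 0.481 ± 0.0346 CPM (SD, n = 3). F27C1.1 kept its call in each of the 9 fits that left out 1 library, and the other 9 lost theirs without control replicate 1 or without control replicate 3, with a highest adjusted p from 0.0624 for ssq-2 to 0.158 for bli-1. Of these 9, 7 also lost the call without control replicate 2, and 5 (col-49, rol-1, Y47G6A.15, col-138 and bli-1) without any 1 of the MNA libraries. These 5, gipc-2 and col-133 lost the call also in limma-voom and when the 6 libraries were fitted alone, with a limma-voom adjusted p from 0.0711 for gipc-2 to 0.103 for col-138.

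Sperm genes were higher under nicotinic acid. Of 20 in the list 9 rose and 0 fell, with 10 and 1 adjusted over the list alone, a median of 0.59 and a mean of 1.395 (camera adjusted p = 1.79e-08, and adjusted p = 0.5 with an estimated correlation). Examples were nspd-2 at 3.42 (SE 0.65), spe-11, a sperm factor needed by the embryo, at 3.29 (SE 0.72), and spe-15, a myosin of sperm formation, at 0.46 (SE 0.09, edgeR adjusted p = 0.0151). The number of sperm list members that rose was 1 without control replicate 1, 5 without control replicate 2, 0 without control replicate 3 and 4 without nicotinic acid replicate 1. In single genes, spe-15 lost its call without control replicate 3 or nicotinic acid replicate 1 (highest adjusted p = 0.0534), nspd-2 without control replicate 1 or 3 (0.0728) and spe-11 without any 1 control (0.0891). Under MNA 0 of the 20 sperm genes passed in edgeR, DESeq2 or limma-voom, 2 had an unadjusted p below 0.05, and the camera adjusted p was 0.455.

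Muscle genes had 3 of 26 higher under nicotinic acid and 5 adjusted over the list alone, with 24 above 0 (camera adjusted p = 6.96e-07, and adjusted p = 0.688 with an estimated correlation). These were the myosin light chain gene mlc-1 at 0.39, the troponin T gene mup-2 at 0.35 and unc-87 at 0.38. The call of mlc-1 was lost without control replicate 1 (adjusted p = 0.0706), and those of mup-2 and unc-87 without any 1 control or nicotinic acid replicate 2 or 3 (highest 0.0873 and 0.113). In the body wall and pharyngeal muscle list 6 rose without MNA replicate 3 or nicotinic acid replicate 1, 0 without control replicate 1, and 1 without control replicate 2 or 3 or nicotinic acid replicate 2 or 3. The glutathione S-transferases had 3 of 41 higher and 1 lower, with 7 and 1 adjusted over the list alone and 35 above 0 (camera adjusted p = 0.000335, and adjusted p = 0.5 with an estimated correlation). In the glutathione S-transferase family 0 rose without control replicate 1 or 2 or nicotinic acid replicate 1 or 3, 1 without MNA replicate 1 or nicotinic acid replicate 2, and 0 fell without control replicate 1 or 3. The genes that rose, gst-12, gst-10 and gst-28, lost their calls in 5, 7 and 7 of the 9 fits that left out 1 library. The highest adjusted p was 0.178 for gst-10 and 0.161 for gst-28. The superoxide dismutase gene sod-3, a target of DAF-16, rose from 1.32 ± 0.429 to 3.20 ± 0.0346 CPM (SD, n = 3; log2 fold change 1.28, SE 0.24, edgeR adjusted p = 0.012). The list of 21 DAF-16-activated genes did not follow it, with 1 higher, 1 lower, 6 above 0 and a median of -0.226 (camera adjusted p = 0.263).

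Cytosolic ribosomal protein genes had 0 of 79 past the threshold in edgeR, 2 in DESeq2, 1 in limma-voom and 19 at an unadjusted p below 0.05, with 78 above 0 and a median of 0.11 (camera adjusted p = 1.01e-11, and adjusted p = 0.688 with an estimated correlation). Oxidative phosphorylation had 0 of 45 past it in edgeR, DESeq2 and limma-voom and 15 at an unadjusted p below 0.05, with 45 above 0 and a median of 0.09 (camera adjusted p = 1.27e-06, and adjusted p = 0.5 with an estimated correlation). Neuropeptide genes had 2 of 100 higher and 1 lower (camera adjusted p = 0.000122, and adjusted p = 0.88 with an estimated correlation). The gene that fell, nlp-39, was at -3.69 (SE 0.45, edgeR adjusted p = 0.00143) and kept its call in those fits. Of the neuropeptide genes 0 rose without control replicate 1 or 2 or nicotinic acid replicate 2 or 3, 1 without MNA replicate 2, 3 without control replicate 3 and 4 without MNA replicate 3. The 2 that rose, flp-9 and nlp-80, lost their calls in 5 and 6 of the 9 fits (highest adjusted p = 0.115 and 0.11). Lysozyme genes had 2 of 11 lower (camera adjusted p = 0.0105, and adjusted p = 0.604 with an estimated correlation), a call lost without nicotinic acid replicate 2 (adjusted p = 0.231). Zygotic embryonic genes, transcribed by the embryo itself, had 4 of 28 lower and 5 adjusted over the list alone, such as the hunchback-like regulator hbl-1 at -1.86 (SE 0.32). The camera adjusted p of that list was 0.016, with an adjusted p = 0.5 with an estimated correlation, and 0.0563 without control replicate 1. The call of hbl-1 was lost without control replicate 1, control replicate 3 or nicotinic acid replicate 3 (highest adjusted p = 0.0889), and of the zygotic embryonic list 0 were lower without control replicate 1, 1 without control replicate 3 or nicotinic acid replicate 1, and 2 without nicotinic acid replicate 3.

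Among the largest falls under nicotinic acid were ins-19 from 7.02 ± 1.41 to 0.950 ± 0.836 CPM (SD, n = 3; log2 fold change -3.02, SE 0.46, edgeR adjusted p = 0.00964), col-121 at -3.01, pqn-73 at -3.01 and dsl-6 at -2.91. The other 6 were R09E10.5, Y41D4B.6, rocf-1, dpy-14, ifa-3 and mtre-1, from -2.73 to -2.44. The calls of ins-19, Y41D4B.6 and rocf-1 held in each of the 9 fits that left out 1 library. The other 7 were lost without control replicate 1, and 6 of these also without control replicate 3 or nicotinic acid replicate 3, with a highest adjusted p from 0.0516 for ifa-3 to 0.168 for mtre-1. Removing nicotinic acid replicate 2 ended the calls of dpy-14 and mtre-1, removing nicotinic acid replicate 1 that of mtre-1, removing control replicate 2 that of dpy-14, and removing an MNA library those of col-121 and dpy-14, with mtre-1 for MNA replicate 3. In limma-voom mtre-1 lost its call, and when the 6 libraries were fitted alone col-121, pqn-73, dsl-6, R09E10.5, dpy-14 and ifa-3 did.

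Across all genes 272 rose and 475 fell under nicotinic acid (edgeR quasi-likelihood, Benjamini-Hochberg), 160 and 162 of them by at least 2-fold. The unadjusted p was below 0.05 for 2686 genes, and the libraries did not overlap for 3159 (22.6%, where chance gives 10%). Without control replicate 1, 88 of 254 changed genes were higher. There were 144 higher and 254 lower without control replicate 3, 171 and 253 without nicotinic acid replicate 1, and 267 and 312 without nicotinic acid replicate 3. The total was 388 when the 6 libraries were fitted alone. Camera called 14 of 44 lists (11 up, 3 down). With an estimated correlation it called 0, with 3 at an unadjusted p below 0.05, while fry called 2. These were the PMK-1-dependent immune effectors (fry adjusted p = 0.0411) and the collagens (0.049), and not the sperm list (0.112).

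**Figure D2:**
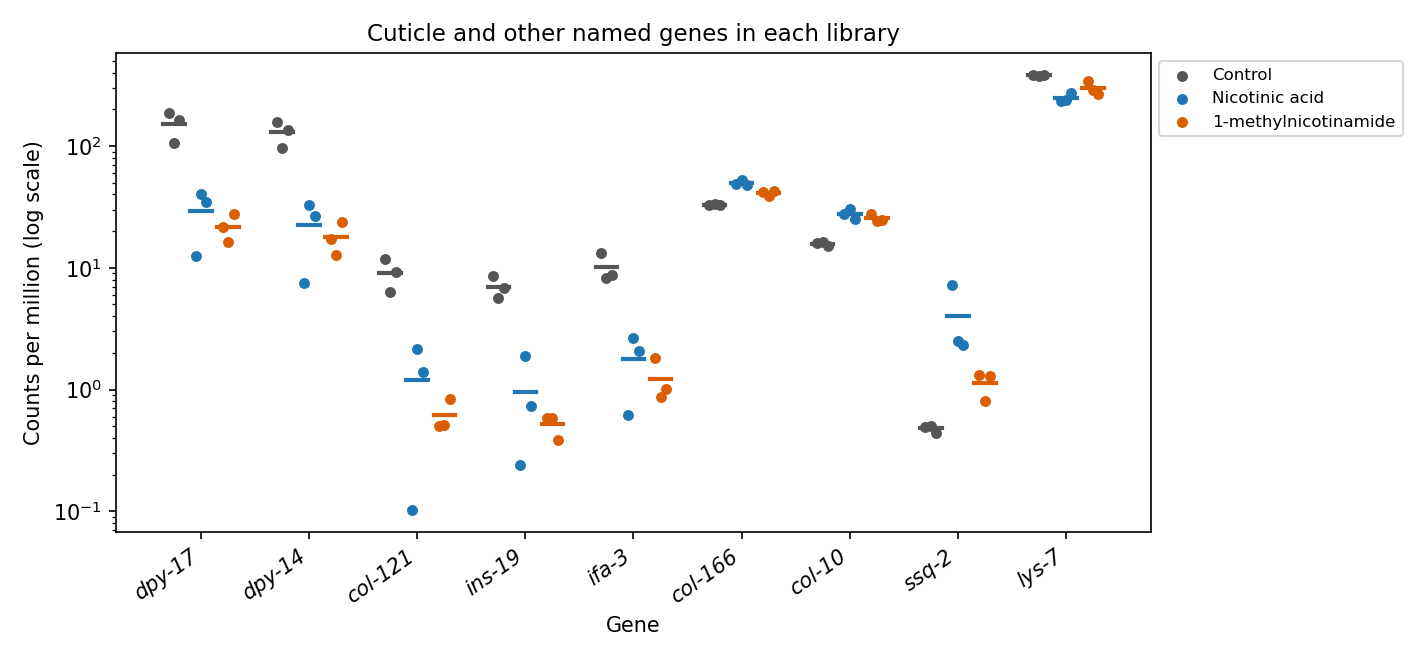
CPM on a log scale for 9 named genes, with 1 point per library and a bar at the mean of each group of 3. For dpy-17 the means were 153 CPM in control, 29.01 under nicotinic acid and 21.7 under MNA, and for col-166 they were 33.1, 49.4 and 41.4.

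Of 27 NAD metabolism genes, 0 passed in each of the 3 comparisons in edgeR, DESeq2 and limma-voom. An unadjusted edgeR p below 0.05 was found for 5 under nicotinic acid, 3 under MNA and 4 between the compounds, and the camera adjusted p was 0.821, 0.6 and 0.228. The sirtuin gene sir-2.1 was at 0.02 under nicotinic acid (95% interval -0.07 to 0.11) and -0.02 under MNA (95% interval -0.10 to 0.07). The methyltransferase gene anmt-1, whose product makes MNA, was at -0.10 (95% interval -0.50 to 0.30) and -0.08 (95% interval -0.48 to 0.32). The nicotinamidase gene pnc-1 was at 0.13 (95% interval -0.03 to 0.30) and -0.12 (95% interval -0.29 to 0.04), and nprt-1, which uses nicotinic acid, at -0.04 (95% interval -0.14 to 0.07) and -0.11 (95% interval -0.21 to -0.01). The oxidase gene gad-3 was at -0.15 and -0.25, gcs-1, the first enzyme of glutathione synthesis, at 0.05 and 0.14, the catalase gene ctl-2 at -0.17 and 0.07, and sams-1 at 0.14 and 0.04, each with an edgeR adjusted p from 0.16 to 0.798. The heat shock gene hsp-16.2 had 0 to 6 counts per library and was not tested.

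Nicotinic acid and MNA were set side by side, at doses that differ, to ask where the carboxylic acid and the methylated amide gave different transcripts. The largest difference was in gst-35, at 1.11 ± 0.346 CPM under nicotinic acid and 71.2 ± 27.5 CPM under MNA (SD, n = 3; log2 fold change of nicotinic acid against MNA -5.96, SE 0.43, edgeR adjusted p = 0.00144). For fmo-5 the difference was -4.39 (SE 0.35, edgeR adjusted p = 0.00256), for cyp-29A3 -4.13 (SE 0.27, edgeR adjusted p = 0.000144) and for gst-4 -0.70 (SE 0.11, edgeR adjusted p = 0.00569). The 10 largest falls were gst-35, gst-21, F49E12.10, ugt-37, irg-6, fmo-5, C32H11.4, the C-type lectin gene clec-143, cyp-29A3 and cyp-32B1, and all 10 kept their calls in each of the 9 fits that left out 1 library. In limma-voom 5 of them lost the call: gst-35 (adjusted p = 0.0507), F49E12.10 and ugt-37 (0.0539 each), cyp-32B1 (0.0581) and irg-6, which lost it also when the 6 libraries were fitted alone (highest adjusted p = 0.119).

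By list, 9 of 41 glutathione S-transferases were lower under nicotinic acid than under MNA and 0 higher, with 15 and 3 adjusted over the list alone (camera adjusted p = 3.31e-10, and adjusted p = 0.0753 with an estimated correlation). Of 37 SKN-1 genes 9 were lower (camera adjusted p = 1.75e-10, and adjusted p = 0.0753 with an estimated correlation), 5 of the SKN-1 and oxidative stress response list without MNA replicate 2 or nicotinic acid replicate 2. Of 20 PMK-1-dependent immune effectors 8 were lower and 12 adjusted over the list alone, such as irg-6 at -5.19 and catp-3 at -0.67 (SE 0.10). Its camera adjusted p was 6.62e-17, with an adjusted p = 0.0628 with an estimated correlation. Without nicotinic acid replicate 1 there were 3 lower in the PMK-1-dependent immune effectors, 4 without nicotinic acid replicate 2 or MNA replicate 2, and 5 without MNA replicate 1. Of 14 DAF-16-repressed genes 5 were lower, the 1 list called also with an estimated correlation (camera adjusted p = 4.51e-14, and adjusted p = 0.0115 with an estimated correlation), with a median of -0.064 and a mean of -0.763. Of 63 cytochrome P450 genes 9 were lower (camera adjusted p = 8.27e-06, and adjusted p = 0.0753 with an estimated correlation) and of 60 UDP-glucuronosyltransferases 7 were lower and 1 higher (camera adjusted p = 0.012, and adjusted p = 0.268 with an estimated correlation). Both tests pointed down while the medians were 0.003 and 0.005 and the means -0.382 and -0.26, and the first median was 0 under DESeq2 size factors. Without nicotinic acid replicate 2 or 3 there were 5 lower in the cytochrome P450 family, and without MNA replicate 2 or nicotinic acid replicate 1 there were 4 in the UDP-glucuronosyltransferase family (3 higher without MNA replicate 3), whose call was lost without nicotinic acid replicate 3 (adjusted p = 0.069).

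Higher under nicotinic acid than under MNA were sperm genes, with 1 of 20 past the threshold and 10 adjusted over the list alone (camera adjusted p = 1.62e-08, and adjusted p = 0.268 with an estimated correlation). The fertilisation gene fer-1 was at 1.11 (SE 0.24, edgeR adjusted p = 0.0397), a call lost in 7 of the 9 fits that left out 1 library, the exceptions being control replicates 1 and 2 (highest adjusted p = 0.197). Collagens had 6 of 112 higher and 1 lower, with 28 and 12 adjusted over the list alone (camera adjusted p = 0.000455, and adjusted p = 0.476 with an estimated correlation). That call was lost without nicotinic acid replicate 1 (adjusted p = 0.351). Of the collagen family 0 were higher without MNA replicate 1 or 2, 11 without MNA replicate 3, 3 without nicotinic acid replicate 1 or 3, and 2 without nicotinic acid replicate 2. In it 3 were lower without control replicate 2 and 5 without MNA replicate 3. Propionate shunt genes had 0 of 7 past the threshold in edgeR and limma-voom, 4 in DESeq2, 5 at an unadjusted p below 0.05 and 4 adjusted over the list alone (camera adjusted p = 6.72e-06, and adjusted p = 0.154 with an estimated correlation). In the propionate shunt 4 passed without MNA replicate 3. Moulting genes had 0 of 34 past the threshold in edgeR and limma-voom, 3 in DESeq2, 15 at an unadjusted p below 0.05 and a median of -0.47 (camera adjusted p = 2.22e-07, and adjusted p = 0.372 with an estimated correlation). None of the 10 largest rises, from col-88 at 2.05 to col-176 at 0.92, kept its call in all of those fits (0 of 10), and these 2 genes lost it without MNA replicate 1, MNA replicate 2 or nicotinic acid replicate 3 (highest adjusted p = 0.192 and 0.211). In limma-voom 6 of the 10 lost the call (col-88, col-60, F53B6.4, K09F6.3, snf-5 and F15B9.6).

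Between the compounds 44 genes were higher and 154 lower under nicotinic acid (edgeR quasi-likelihood, Benjamini-Hochberg), with an unadjusted p below 0.05 for 1897, and 2671 genes (19.1%, where chance gives 10%) had libraries that did not overlap. Without MNA replicate 1 there were 1 higher and 85 lower, without MNA replicate 2 1 and 75, and without MNA replicate 3 160 and 258. Without nicotinic acid replicate 1 there were 20 and 107, and 27 and 134 without control replicate 3. There were 28 higher and 94 lower without nicotinic acid replicate 2, and 33 and 89 without nicotinic acid replicate 3. Camera called 23 of 44 lists (9 up, 14 down), 1 of them with an estimated correlation, while fry called 8. Among these were the DAF-16-repressed genes (fry adjusted p = 0.00365) and the PMK-1, SKN-1 and glutathione S-transferase lists (0.0112 each). The sperm list was not called by fry (adjusted p = 0.0842).

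Against control, 333 genes were lower under both compounds, 89 higher under both and 0 opposite. Independent lists of these sizes would share 17.9 lower and 9.9 higher genes. Simulations of unchanged groups with common controls gave 0 and 0, but called at most 3 genes lower in a comparison, so these values decide nothing. With unrelated effects and common controls, the simulations gave 39 to 64 genes lower in both, 41 to 72 higher in both and 60 to 100 opposite. The observed 333 and 89 lay above these ranges, the 89 by less, and the observed 0 opposite lay below. These simulations called at least 723 and 702 genes lower per comparison, against 475 and 528 observed. The genes lower under both had a median of 15.4 CPM in control, and of 55.1% of control under nicotinic acid and 56.3% under MNA. For 114 of them the level was at most 50% of control under both compounds, and 1 differed between the compounds. For ifa-3 the difference between the compounds was 0.50 (SE 0.52), and for dpy-17 0.40 (SE 0.48). Of the 325 genes changed under nicotinic acid alone 28 differed between the compounds, and of the 614 changed under MNA alone 137 did. Across genes, which are not independent replicates, the fold changes against control had a Pearson r of 0.675 and a Spearman rho of 0.617. The simulations of unchanged groups gave a mean r of 0.51 and a highest r of 0.551. The covariance was 0.1531 against their mean of 0.0243, a difference of 0.1288. The 3 controls cannot be divided into separate sets of 2 libraries, so that part of the excess over independent lists can come from the shared controls. In all these simulations each gene was drawn independently, so many genes shifted together in the shared controls are not covered.

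**Figure D3:**
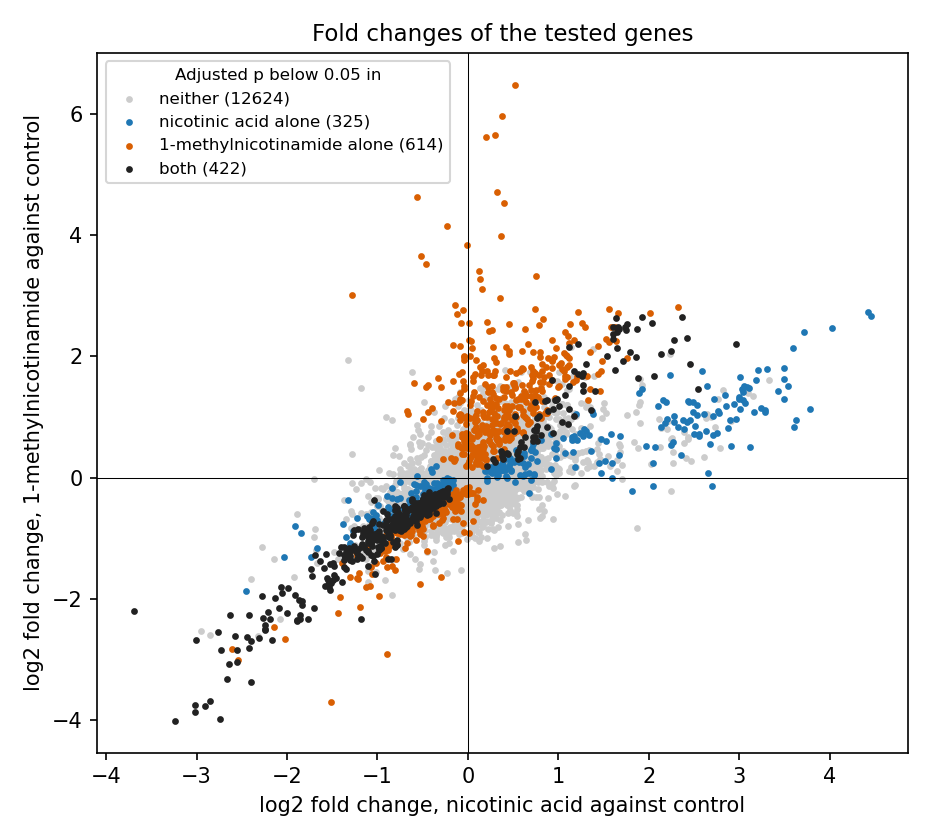
The log2 fold change of nicotinic acid against control on the horizontal axis and of MNA against control on the vertical axis, with 1 point per tested gene coloured by whether its adjusted p was below 0.05. The 422 genes past it in both lie in 2 of the 4 quadrants, with 0 in opposite directions, and the 614 genes past it under MNA alone include gst-35 at 6.48.

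**Figure D4:**
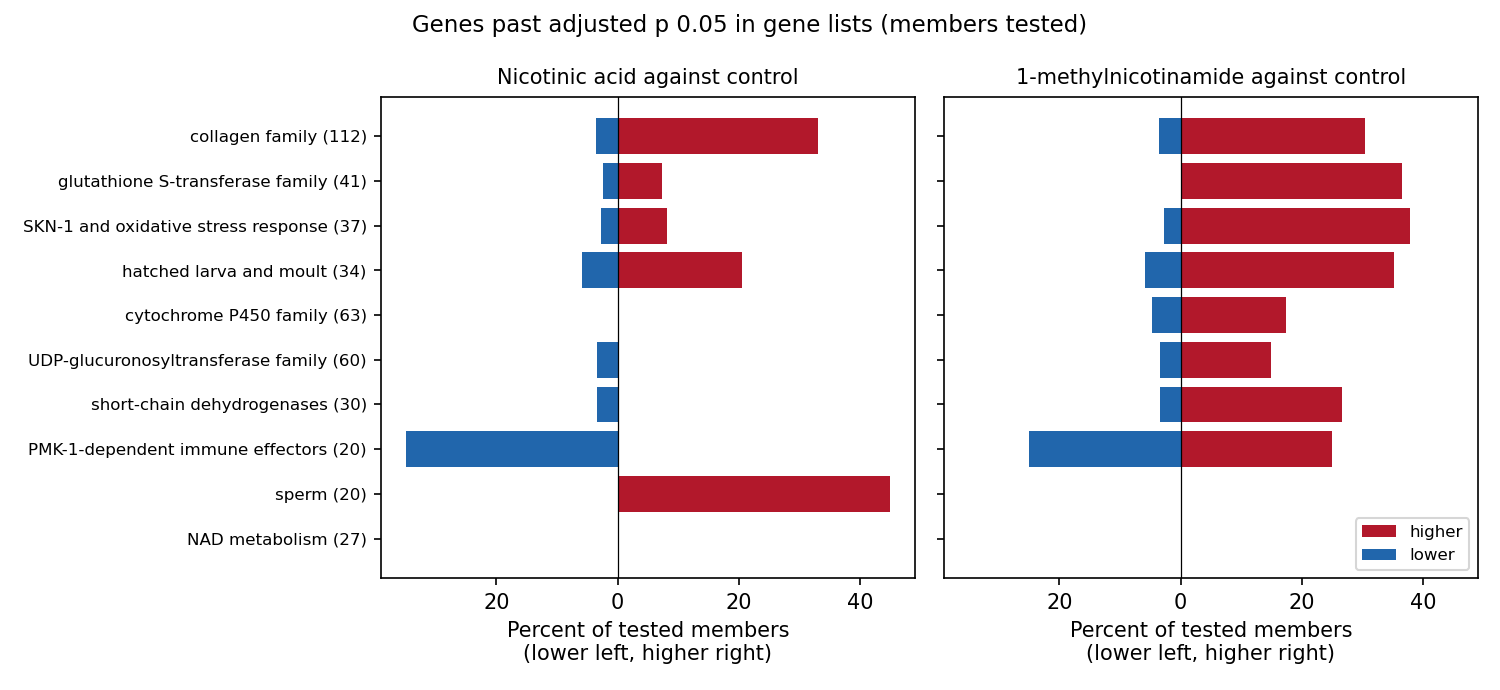
Percent of the tested members of 10 gene lists that were higher (right) or lower (left) against control at an adjusted p below 0.05, for nicotinic acid and for MNA. Of 41 glutathione S-transferases 15 rose under MNA and 3 under nicotinic acid, where in the glutathione S-transferase family 0 rose without control replicate 1 or 2 or nicotinic acid replicate 1 or 3, and of 27 NAD metabolism genes 0 passed in either.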

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

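The tests of nicotinic acid replicate 1 alone and of late larvae were chosen only after the result was seen, and the criterion of the second was widened after its first outcome, to count the comparison with control too.

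Major sperm protein genes, which encode the main cytoskeletal protein of sperm, lay under the low-count filter (0 of 31 tested) and gave a signal above control when summed. The sum was 3.31 ± 2.61 CPM under nicotinic acid, 0.385 ± 0.179 CPM in control and 1.02 ± 0.113 CPM under MNA (SD, n = 3). It stood at 6.296, 2.162 and 1.472 CPM in the nicotinic acid libraries, from 181, 40 and 46 counts, each above the highest control of 0.488 CPM. The MNA libraries, at 1.125, 1.037 and 0.9 CPM, were each above that control too.

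The tested sperm list moved the same way, with a median log2 fold change of 0.586 under nicotinic acid. Nicotinic acid replicate 1 as the sole source was argued against, since the median without that library was 0.413, with 18 of 21 members above 0 and 4 past the threshold. Males among the animals stay open: the summed counts of 10 male genes were 1.31 times the control mean (2.94 ± 0.557 against 2.26 ± 0.0611 CPM, SD, n = 3; MNA 2.64), between the bounds of 1.2 and 1.5 set beforehand, and 4 of the 10 were tested, with try-5 also in the sperm list. On the same summed measure the sperm list stood at 82.6 ± 17.9 CPM under nicotinic acid against 61.7 ± 1.51 CPM in control (SD, n = 3). Under MNA that sum was 62.7 ± 4.47 CPM (SD, n = 3). Late larvae, which make sperm, cannot be told apart either, because 16 moulting genes had a median of -0.409 for nicotinic acid against MNA but of 0.247 against control, at percentile 100 of random lists matched on expression, and 0.646 for MNA against control. Of those 16 genes 15 are also in the hatched larva and moult list, so this is not separate evidence from that list. The random lists were not matched on how genes vary together, so the percentile can overstate the difference. Per library, as a median deviation on the log2 scale, the 16 genes stood at -0.295 in nicotinic acid replicate 3, within the controls (-0.307 to -0.177), where the sperm list stood at 0.403, and at 0.215 to 0.343 in the MNA libraries, where the sperm list stood at -0.377 to 0.052. In nicotinic acid replicates 1 and 2 the 16 genes stood above the controls (0.072 and 0.2). The collagen family stood at 0.06 in nicotinic acid replicate 3, above the controls (-0.54 to -0.442), and at 0.056 to 0.166 in the MNA libraries. These values point in different directions and rest in part on 1 library, so they do not decide on late larvae. An action of nicotinic acid on sperm genes may be a further cause and was not tested apart from these.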

How the results depend on the processing

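The fit without ribosomal RNA genes was chosen only after the data were seen; it gave 755 and 1037 genes against control and kept the calls of all 312 results for named genes and comparisons. Under the other alternatives 0 of these 312 changed direction while past the threshold in the main fit or the alternative. Changes of sign in results past it in neither were not counted. Of 163 past the threshold, 71 fell below it in some fit without 1 library and 81 under some other alternative. A further 48 results gained a call under some alternative.

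For nicotinic acid against control the count of 747 genes was 388 with the 6 libraries fitted alone, 134 at a threshold of 0.01 and 1206 at 0.1, and 322 or 350 on RPKM with 1 or 0.1 added, and ran from 254 to 758 without 1 library. For MNA against control the count of 1036 was 361 at 0.01 and 648 or 607 on RPKM, and ran from 369 to 1195. Between the compounds the count of 198 was 431 with no filter, 394 in DESeq2, 80 at 0.01, 376 at 0.1 and 108 or 101 on RPKM, and ran from 76 to 418. A threshold changes a count by construction. For the libraries left out, the filter, DESeq2 and RPKM the cause was not tested, and removing a library both lowered and raised counts. The share of changed genes that were higher was 36.4% for nicotinic acid, 49% for MNA and 22.2% between the compounds; on RPKM with 0.1 added it was 50.3%, 61.1% and 9.9%, and without 1 library it ran from 26.4% to 46.1%, 38.4% to 61.8% and 1.2% to 38.3%. Under other scalings the median log2 fold change of all genes lay from -0.007 to 0.028, against -0.003 to 0.003 in the main fit.

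The number of lists was 14, 16 and 23 in the 3 comparisons, in the order above. With an estimated correlation it was 0, 0 and 1, with fry 2, 9 and 8, with its mixed form 32, 32 and 30, and at 0.01 it was 10 for MNA and 14 between the compounds. Without 1 library it ran from 10 to 18, 14 to 17 and 19 to 23. Of the lists called, 8 of 14, 10 of 16 and 13 of 23 kept the call without any 1 library. The correlation of the fold changes, 0.675, was 0.565 with no filter and ran from 0.596 to 0.717 without 1 library; the cause was not tested.

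The replicate numbers did not pair the libraries alike in all groups. Correlations of residuals ran from -0.2 to 0.16 for equal numbers and from -0.11 to 0.16 for others. Between control and MNA they ran from 0.05 to 0.16 for equal numbers and from -0.11 to 0.02 for others. Between nicotinic acid and control they were -0.05, -0.2 and 0.08 for equal numbers and from -0.11 to 0.16 for others. Between nicotinic acid and MNA they were 0.03, 0.02 and 0.11 for equal numbers and from -0.08 to 0.05 for others. In both other groups 4 of 9 libraries were closest to their own number. These included every library of replicate number 3, with correlations of 0.08, 0.11 and 0.16 between them. A shared effect of the replicate number therefore stays open. With a replicate block the counts were 738, 1056 and 285 genes, and of the 10 largest changes per direction 6 rises and 7 falls under nicotinic acid, 6 falls under MNA and 3 rises between the compounds lost their call. In the 10 splits of each set of 6 libraries into groups of 3, 1 split, the real one, gave as many genes; the real values were 747, 1036 and 198 and the highest other was 0 in each, and 10 splits are too few for a share under 0.05. The detection floor of 3 counts was 0.096 to 0.162 CPM, and whether depth limits the detection of small changes was not tested.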

Other observations

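The tests of late embryos and of unchanged groups with common controls were set before their result was seen, although the list of embryonic genes was written after the largest falls were known. The tests of gene lengths, of unrelated effects with common controls and of the embryonic list without its members lower in both comparisons were chosen only after the result was seen.

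Several gene groups are not described above. Nuclear receptor genes, which encode ligand-gated transcription factors, had 4 higher, 3 lower and 179 that did not pass under MNA, with a median of -0.14 (camera adjusted p = 0.0169, and adjusted p = 0.826 with an estimated correlation), a call lost without control replicate 1, control replicate 3 or MNA replicate 2 (highest adjusted p = 0.11). In the nuclear hormone receptor family 10 were lower without MNA replicate 3, 6 without control replicate 2, 5 without nicotinic acid replicate 1, 2 without control replicate 1 or 3, 1 without MNA replicate 1 and 0 without MNA replicate 2. Of those higher, 2 were left without any 1 control, MNA replicate 1 or 2 or nicotinic acid replicate 3. Metal response genes had 2 of 13 higher and 1 lower under MNA (camera adjusted p = 0.0473, and adjusted p = 0.618 with an estimated correlation), with cdr-6 at 1.41 (SE 0.15) and the ferritin gene ftn-2 at -0.26 (SE 0.06). That list call was lost in 6 fits without 1 library (control replicates 2 and 3, MNA replicate 1 and each nicotinic acid replicate, highest adjusted p = 0.283) and under DESeq2 size factors (adjusted p = 0.0526), and that of ftn-2 without control replicate 1 or 3 or MNA replicate 1 or 2 (highest adjusted p = 0.128). Acid phosphatase genes were called up under both compounds (camera adjusted p = 0.0394 for nicotinic acid and 0.0473 for MNA, and adjusted p = 0.5 and 0.352 with an estimated correlation). Each lost the call in 5 or 6 of the 9 fits: the first without control replicate 1 or 2 or any 1 nicotinic acid replicate (highest adjusted p = 0.0944), the second without control replicate 1 or 2, MNA replicate 1 or 3 or nicotinic acid replicate 1 or 3 (highest adjusted p = 0.151). Other scaling ended the first with library size alone (adjusted p = 0.051) and the second with DESeq2 size factors (0.0514).

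Under nicotinic acid the tricarboxylic acid cycle list had 0 of 24 past the threshold in edgeR, DESeq2 and limma-voom and 2 at an unadjusted p below 0.05, with 22 above 0 (camera adjusted p = 0.0105, and adjusted p = 0.88 with an estimated correlation), and was lost without control replicate 3 or nicotinic acid replicate 2 (highest adjusted p = 0.282). Mitochondrial ribosomal proteins had 0 of 69 past it in edgeR, DESeq2 and limma-voom, 4 at an unadjusted p below 0.05 and a camera adjusted p = 0.00996 (adjusted p = 0.935 with an estimated correlation, lost without control replicate 1 or nicotinic acid replicate 1, highest adjusted p = 0.338). Neuron genes had 0 of 26 past it in edgeR and limma-voom, 1 in DESeq2, 10 at an unadjusted p below 0.05 and a camera adjusted p = 0.00629 (adjusted p = 0.886 with an estimated correlation, lost without control replicate 2 or nicotinic acid replicate 2, highest adjusted p = 0.215). Between the compounds, S-adenosylmethionine and one-carbon genes had 1 of 25 higher under nicotinic acid and 6 adjusted over the list alone (camera adjusted p = 0.00115, and adjusted p = 0.135 with an estimated correlation). In the S-adenosylmethionine and one-carbon metabolism list 4 were higher without MNA replicate 3, 3 without control replicate 1 and 0 without any other library. Fatty acid genes had 5 of 48 lower under nicotinic acid than under MNA (camera adjusted p = 0.0131, and adjusted p = 0.413 with an estimated correlation), among them the peroxisomal oxidation genes acox-1.1 at -1.35 (SE 0.21) and daf-22 at -0.65 (SE 0.11). In the fatty acid oxidation and synthesis list 0 were lower without MNA replicate 1 or 2 or nicotinic acid replicate 3, 1 without nicotinic acid replicate 2, 2 without control replicate 2 or nicotinic acid replicate 1, 3 without control replicate 1 or 3, and 9 without MNA replicate 3. That list call was lost without nicotinic acid replicate 3 (adjusted p = 0.0832), and the calls of acox-1.1 in all fits but the one without MNA replicate 3 (highest adjusted p = 0.114) and of daf-22 without MNA replicate 1 or 2 or nicotinic acid replicate 2 or 3 (highest adjusted p = 0.0767). Heat shock and unfolded protein genes had 0 of 23 past the threshold in edgeR in the 3 comparisons, with 5, 5 and 2 at an unadjusted p below 0.05, 2, 0 and 1 in DESeq2 and 0 in limma-voom (camera adjusted p = 0.219, 0.455 and 0.572). Vitellogenins had 0 of 6 past it in the 3 comparisons in each tool, with 1, 1 and 0 at an unadjusted p below 0.05 (camera adjusted p = 0.147, 0.0664 and 0.569). C-type lectins had 11 higher, 9 lower and 84 that did not pass under MNA (camera adjusted p = 0.44). In the C-type lectin family 1 was lower without MNA replicate 1, 0 without MNA replicate 2 and 3 without any 1 control. Neuropeptide genes had 1 of 100 lower under MNA while the list was called up (camera adjusted p = 0.0125, and adjusted p = 0.826 with an estimated correlation), a call lost without control replicate 2 or MNA replicate 3 (highest adjusted p = 0.533).

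Between the compounds, 7 of 30 short-chain dehydrogenases were lower under nicotinic acid (camera adjusted p = 6.13e-10, and adjusted p = 0.0913 with an estimated correlation). Of the short-chain dehydrogenases 4 were lower without MNA replicate 1 or 2 or nicotinic acid replicate 1 or 2, and 3 without nicotinic acid replicate 3. Metal response genes had 1 of 13 higher and 2 lower (camera adjusted p = 0.0033, and adjusted p = 0.268 with an estimated correlation). Muscle genes had 0 of 26 past the threshold in edgeR and limma-voom, 2 in DESeq2 and 9 at an unadjusted p below 0.05 (camera adjusted p = 2.47e-06, and adjusted p = 0.464 with an estimated correlation). In the body wall and pharyngeal muscle list 7 passed without MNA replicate 3. Transthyretin-related genes had 1 of 48 higher (camera adjusted p = 0.011, and adjusted p = 0.268 with an estimated correlation). In the transthyretin-related family 0 were higher without control replicate 3, any 1 MNA library or nicotinic acid replicate 1. The following had 0 past the threshold in edgeR and limma-voom. Hypoxia genes had 1 of 14 in DESeq2 and 6 at an unadjusted p below 0.05 (camera adjusted p = 0.0236, and adjusted p = 0.268 with an estimated correlation). That call was lost without control replicate 3 or nicotinic acid replicate 1 (highest adjusted p = 0.151). Lysozymes had 1 of 11 and 2 (camera adjusted p = 0.012, and adjusted p = 0.338 with an estimated correlation). It was lost without nicotinic acid replicate 2 (adjusted p = 0.297). Intestine genes had 1 of 24 and 6 (camera adjusted p = 0.0235, and adjusted p = 0.268 with an estimated correlation). That call was lost without MNA replicate 3 or nicotinic acid replicate 3 (highest adjusted p = 0.2). Oocyte genes had 0 of 49 and 7 (camera adjusted p = 0.000878, and adjusted p = 0.636 with an estimated correlation). It was lost without nicotinic acid replicate 2 (adjusted p = 0.0669). Zygotic embryonic genes had 0 of 28 and 6 (camera adjusted p = 0.0153, and adjusted p = 0.268 with an estimated correlation). That call was lost without MNA replicate 3 or nicotinic acid replicate 1 (highest adjusted p = 0.15). Mitochondrial ribosomal proteins had 0 of 69 and 2 (camera adjusted p = 0.0235, and adjusted p = 0.694 with an estimated correlation). It was lost without MNA replicate 2 or 3 or nicotinic acid replicate 1 (highest adjusted p = 0.738). Cytosolic ribosomal proteins had 0 of 79 and 0 (camera adjusted p = 0.0488, and adjusted p = 0.787 with an estimated correlation). That call was lost without control replicate 1, MNA replicate 3 or nicotinic acid replicate 1 or 3 (highest adjusted p = 0.786) and under DESeq2 size factors (0.0668).

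Genes lower under both compounds numbered 333. Simulations of unchanged groups with common controls gave 0 such genes, but they called at most 3 genes lower in a comparison, so that this test decides nothing. Shared controls with unrelated effects of the compounds were argued against as the whole source only for genes that vary independently of each other. The 20 simulations of that case gave 64 genes lower in both at most, although they called at least 723 and 702 genes lower per comparison, against 475 and 528 observed. The covariance of the fold changes, 0.1531, lay above the highest of 0.0274 in simulated unchanged groups. Both bounds rest on the settings of the simulations, in which each gene was drawn independently. They do not cover many genes shifted together in the shared controls, so that source stays open. A candidate explanation is fewer late embryos in the treated libraries, because 32 genes of embryonic morphogenesis and cell fate had medians of -0.446 under nicotinic acid and -0.413 under MNA, both at percentile 0 of 10000 lists matched on expression, with 30 and 29 members below 0. Of the 32 genes 6 are themselves among the 333. Without them the medians were -0.401 and -0.329, again at percentile 0, with 24 and 23 of 26 below 0. The random lists were not matched on how genes vary together, so these percentiles can overstate the support. The list was written after the largest falls were known, and leaving out the 6 genes does not undo that choice. Seen per library, which is the same contrast and not further evidence, all 3 controls stood above every treated library for this list. They stood at 0.168 to 0.392 on the log2 scale around the mean of all libraries, against a highest treated value of 0.022. Lower transcription in embryos of unchanged number, or an action of the compounds, was not tested and stays open, and the zygotic embryonic list was called for nicotinic acid (camera adjusted p = 0.016, and adjusted p = 0.5 with an estimated correlation, lost without control replicate 1, adjusted p = 0.0563) but not for MNA (0.726).

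The deposited RPKM values may rest on gene lengths out of register with the gene names. Among 13940 protein-coding genes after a block of 15 telomeric genes in the table, the implied length lay within 3% of the annotated exon length of the gene 15 places above for 54.2% and of the gene itself for 1.7%. Before that block the shares were 1.7% and 29.6%. A fold change between libraries within a gene is not altered by a wrong length except through the value added before the logarithm, but RPKM cannot be compared between genes.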
